A study of Mus musculus with 2 samples.

How the data were processed

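Total RNA-seq libraries from the gastrocnemius of 2 male mice of the hybrid strain B6CASTF1/J, 4 days old, were analysed as 1 group of 2 biological replicates. The replicate numbers and the separate animal numbers come from the labels. Per the labels, RNA was purified with a column kit for animal tissue, 300 ng entered each library, and ERCC spike-in controls were added with a profile meant for stranded, ribosome-reduced libraries. The aligner, the quantification programs and their versions are not given in the sources used here. The genome build is mm10 and the annotation GENCODE M21, per the notes deposited with each library.

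The deposited gene and transcript tables hold expected counts, which need not be whole numbers, and their columns carry the names that RSEM writes, per the file headers. The same deposited tables give TPM, which the authors' quantifier scaled to a fixed sum over all entries, spike-ins included, after dividing by an effective length of the length minus 99 nt. Per the file headers, the transcript tables also give the percent of its gene that each transcript holds, and the gene tables give bounds of an interval for TPM whose level is not stated. These bounds need not contain the TPM itself. A second deposited transcript table holds estimated counts and TPM under column names that kallisto writes, per the file headers, and was made directly from reads, per the deposited notes. There the effective length was a median of 349 nt below the length for transcripts over 2000 nt. There 77 of 79 genes shorter than 300 nt, of those with a mean expected count of 100 or more, have under 1 estimated count over both libraries. Whether counting used strand is not stated, so values of overlapping and antisense genes are uncertain, as are those of near-identical copies, whose reads are split by estimation.

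The gene table has 81881 entries: 55536 annotated genes, all of which matched the annotation, 96 ERCC controls, 26248 entries with a bare number for a name, and 1 phiX174 control sequence. The numbered entries, which name no gene, held 4 counts in replicate 1 and 6 in replicate 2 and were left out of library sizes and tests. Spike-ins and the phiX174 sequence were left out of the genes. The transcript tables have 168207 and 141864 entries. Where a symbol had more than 1 gene identifier, which was so for 115 symbols, levels, shares, pairs and lists used the identifier with the higher count. Numbers of genes, correlations, the coefficient of variation and the genes of largest ratio kept every identifier. All expected counts summed to 35512215 in replicate 1 and 32507943 in replicate 2, and the estimated counts of the second quantification to 34695571 and 31725605. The limit that a count of 0 allows was taken as 3 counts in that library. Counting intervals are exact (Clopper-Pearson) 95% intervals of the split of a gene's counts between the libraries. Reads were not marked with molecular identifiers in these files, so intervals and limits cover counting error only.

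Levels are TPM of the alignment-based gene table. Shares of the 6 sarcomeric myosin heavy chain genes are percent of their summed TPM. Log2 ratios of 18 gene pairs and list medians on the log2 scale used TPM plus a pseudocount of 0.1, which understates differences of very low genes. The 25 gene lists, the pairs, the rule for named genes and the alternatives were fixed before the data were examined. The rule named all myosin heavy chain genes and pair members, the 15 genes of highest mean TPM, up to 4 members of highest mean TPM in each other list with any counted member under 0.1 TPM in both libraries, all sex-linked genes of the list, and the 10 genes of largest ratio between the libraries among those with a mean count of 100 or more. For this ranking no prior count was added and a count of 0 was set to the limit of 3 counts. For transcripts it named the leading transcript of contractile and pair genes. The level of 1 gene that the rule names is not reported here. A further 8 lists, for melanocytes, myelin, immature or non-myelin Schwann cells, later-rising muscle genes, early muscle genes, hindlimb and forelimb patterning and muscle growth signalling, were written after the files were opened.

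Between-library ratios used expected counts, scaled by the trimmed mean of M-values in edgeR 4.0.16 (R 4.3.3), with a prior count of 0.5. Counts were rounded to whole numbers for edgeR, DESeq2 and the counting intervals, but not for the ratios. Genes with a mean count of 10 or more entered the list comparisons and the common biological coefficient of variation, estimated by edgeR with an intercept-only design. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. This percentile describes the 2 libraries and is no test between conditions. The number of genes over 2-fold among those with a mean count of 100 or more was set beside 100 simulated Poisson pairs. No p per gene was computed, since there is no second group. Other calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

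The steps were tested on simulated data. In a simulated pair with 200 of 12421 genes changed 4-fold, all 200 were recovered and 0 unchanged genes were counted. This checks the counting step only. It gives no rate of unchanged genes over 2-fold at the spread between the animals (coefficient of variation 0.2003 at a mean count of 100 or more). Of 100 lists of 10 genes drawn at random from 17998 genes, 3 lay beyond the middle 95%, and a list shifted by 2-fold lay at percentile 100. The edgeR estimate was 0.200 for counts simulated with a coefficient of variation of 0.2 and 0.00988 for Poisson counts. Alternatives were the second quantification, the posterior mean TPM, counts not divided by length, a pseudocount of 1 TPM, other minimum levels, size factors from DESeq2 1.42.0, scaling to the ERCC total, and leaving out each library. Counts and ratios without skin gene families were added after seeing the data.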

Results

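Total RNA was sequenced from the gastrocnemius, the large superficial muscle of the calf, of 2 male mice at 4 days of age. Both animals were first-generation offspring of a cross between C57BL/6J and CAST mice, and the labels list them as separate biological replicates of 1 group. Each library was made from 300 ng of RNA with ERCC spike-in controls. Replicate 1 held 35281187 expected counts in annotated genes and replicate 2 held 32301531. Transcript abundance normalised for length and depth (TPM) was 1 or more in both libraries for 13579 genes, with 13987 in replicate 1 and 14472 in replicate 2. Because there was no second group, genes were compared within each library and the 2 animals were compared with each other. With 1 library per animal, a difference between the animals cannot be told apart from one of dissection or library preparation. Values are given as mean ± SD over the 2 libraries (n = 2) unless a replicate is named. An exact two-sided sign-flip test of 2 values cannot go below p = 0.5, so no test between means was made.

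The muscle RNA was led by structural noncoding RNAs, mitochondrial transcripts and contractile genes of skeletal muscle. Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, stood at 150947 ± 3916 TPM each, and Rn7sk, the RNA that holds back the elongation factor P-TEFb, at 35640 ± 1859 TPM. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 reached 42831 ± 3013 and 26331 ± 2187 TPM. Skeletal alpha-actin, Acta1, was the highest protein-coding gene at 13366 ± 531 TPM, followed by the fast regulatory light chain Mylpf at 11514 ± 374 TPM. By the quantification made directly from reads Acta1 and Mylpf stood higher, at 32816 ± 851 and 22328 ± 483 TPM, so TPM levels depend on the quantification. Among the 15 highest genes were also the imprinted noncoding RNA H19 (8035 ± 571 TPM) and the RNase P RNA Rpph1 (7962 ± 1503 TPM). So were mt-Co1 (7008 ± 25.1 TPM), the fast essential light chain Myl1 (6934 ± 386 TPM) and Gm26917 (12719 ± 282 TPM). Gm26917 is annotated as long intergenic noncoding RNA, and where its reads came from was not tested. Rpph1 stood at only 1.30 ± 0.113 TPM by the quantification made directly from reads. The remaining 3 of the 15 were Gm28661, Gm10925 and Gm28437 at 8861 ± 251, 6401 ± 510 and 5396 ± 203 TPM, annotated pseudogenes that lie next to each other on chromosome 1. Rn7s1 and Rn7s2 had the same value in each library, and the split of reads between such copies is uncertain, as it is for the 3 pseudogenes, which match mitochondrial genes.

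Protein-coding genes outside the mitochondrial genome took 75.3% ± 0.416 of expected counts. Mitochondrial ribosomal RNA took 7.15% ± 0.438 and all mitochondrial genes together 9.44% ± 0.489. Genes annotated as long intergenic noncoding RNA took 5.78% ± 0.166. Of these, Gm26917 alone had 977316 counts in replicate 1 and 881836 in replicate 2. Rn7s1, Rn7s2 and Rn7sk took 5.73% ± 0.166 of counts but 33.8% ± 0.597 of TPM, which divides counts by transcript length. Protein-coding genes outside the mitochondrial genome made up 41.8% ± 0.182 of TPM, but 73.3% ± 0.922 by the quantification made directly from reads. The ERCC controls took 0.643% ± 0.0110 of counts. Of these controls 66 had counts in both libraries, and the log2 count ratio of the 28 with a mean count of 100 or more had an SD of 0.10 across controls.

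Perinatal myosin dominated the sarcomeric myosin heavy chains at this age. Myh8, the perinatal heavy chain, made up 76.2% ± 1.13 of the summed TPM of 6 sarcomeric heavy chain genes, at 4679 ± 280 TPM. Myh4, the heavy chain of the fastest adult fibres (type 2B), followed with 10.7% ± 2.89 at 663 ± 226 TPM. Myh1 (type 2X) held 4.01% ± 0.205, the embryonic chain Myh3 3.83% ± 0.867, the slow chain Myh7 3.71% ± 0.744 and Myh2 (type 2A) 1.58% ± 0.0535. The 2 developmental chains Myh3 and Myh8 together made up 80.0% ± 1.99, against 16.3% ± 2.74 for the 3 adult fast chains. These gaps exceed the spread between the animals, whereas the shares of Myh1, Myh3 and Myh7 lie within that spread of each other.

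The 5 developmental and fast genes lie in tandem on the plus strand of chromosome 11 in the mm10 assembly. In order they are Myh3 (67078300 to 67102291), Myh2 (67171027 to 67197517), Myh1 (67200052 to 67224575), Myh4 (67238029 to 67260446) and Myh8 (67277124 to 67308634). Myh7 lies on the minus strand of chromosome 14 (54970684 to 54994626). The largest relative difference between the animals in this family was in Myh4, at 823 TPM in replicate 1 and 503 TPM in replicate 2, whereas Myh3 stood at 208 and 258 TPM and Myh7 at 206 and 247 TPM. Myh1 held 6.44% by the quantification made directly from reads.

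**Figure D1:**
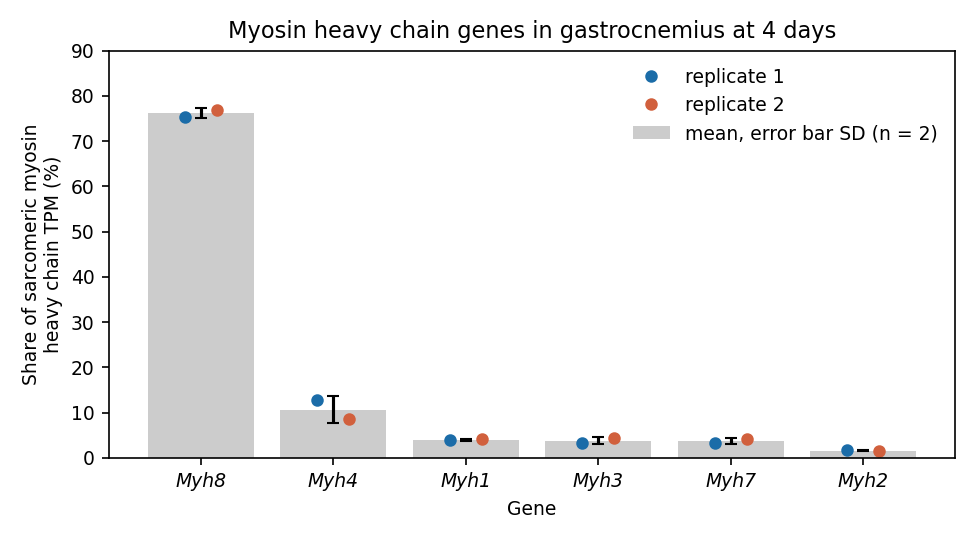
Share of each sarcomeric myosin heavy chain gene in the summed TPM of the 6 genes (percent), with bars for the mean, error bars for the SD (n = 2) and points for each animal. Myh8 stands at 76.2% and Myh4, the next gene, at 10.7%.

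Pairs of related genes were compared within each library, one member used earlier, in slow fibres or outside muscle and the other later, in fast fibres or mainly in muscle. In 16 of 18 pairs the later, fast or muscle-type gene was the higher in both animals. Skeletal Acta1 exceeded cardiac actin Actc1, the actin of early muscle, by 15.8-fold (log2 ratio -3.98 ± 0.46). Muscle creatine kinase Ckm exceeded the brain form Ckb by 197-fold (-7.62 ± 0.05), fast troponin T Tnnt3 exceeded the cardiac and embryonic form Tnnt2 by 59.6-fold (-5.90 ± 0.26), and fast troponin I Tnni2 exceeded slow Tnni1 by 22.4-fold (-4.48 ± 0.38). The exceptions were Chrng, the fetal subunit of the acetylcholine receptor, against adult Chrne (0.68 ± 0.67), and the liver-type cytochrome oxidase subunit Cox7a2 against the muscle-type Cox7a1 (0.98 ± 0.19). The mean lay more than 2 SD from 0 in 17 pairs, and Chrng and Chrne were the pair that did not.

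The other contractile pairs ranged from 2.85-fold to 44.9-fold. Myl1 exceeded the embryonic light chain Myl4 by 44.9-fold (-5.49 ± 0.30), Tnnc2 exceeded slow Tnnc1 by 23.8-fold (-4.58 ± 0.34), and Tnnt3 exceeded slow Tnnt1 by 19.3-fold (-4.27 ± 0.32). The fast calcium pump Atp2a1 exceeded the slow pump Atp2a2 by 21.9-fold (-4.45 ± 0.30), Casq1 exceeded Casq2 by 3.19-fold (-1.68 ± 0.18), and the release channel Ryr1 exceeded Ryr3 by 6.41-fold (-2.68 ± 0.21). Myh8 exceeded Myh3 by 20.2-fold (-4.33 ± 0.31) and Myh4 exceeded Myh7 by 2.85-fold (-1.51 ± 0.69). Among metabolic pairs, muscle enolase Eno3 exceeded Eno1 by 7.51-fold (-2.91 ± 0.03), Pgam2 exceeded Pgam1 by 26.1-fold (-4.71 ± 0.23), and Cox6a2 exceeded Cox6a1 by 2.43-fold (-1.28 ± 0.34). Cox8b exceeded Cox8a by 1.51-fold (-0.60 ± 0.21), but counts not divided by length gave the opposite sign (0.19). All 18 log2 ratios were higher in replicate 2 than in replicate 1, by 0.97 for Myh7 over Myh4 and 0.65 for Actc1 over Acta1. By the quantification made directly from reads the signs were the same in all 18 pairs, with Cox7a2 over Cox7a1 at 2.19, Actc1 over Acta1 at -4.62 and Cox6a1 over Cox6a2 at -0.68. Counts not divided by length gave -3.54 for Pgam1 over Pgam2, -3.52 for Ryr3 over Ryr1, -3.78 for Atp2a2 over Atp2a1, -3.83 for Tnni1 over Tnni2, -1.09 for Casq2 over Casq1 and 1.28 for Chrng over Chrne.

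**Figure D2:**
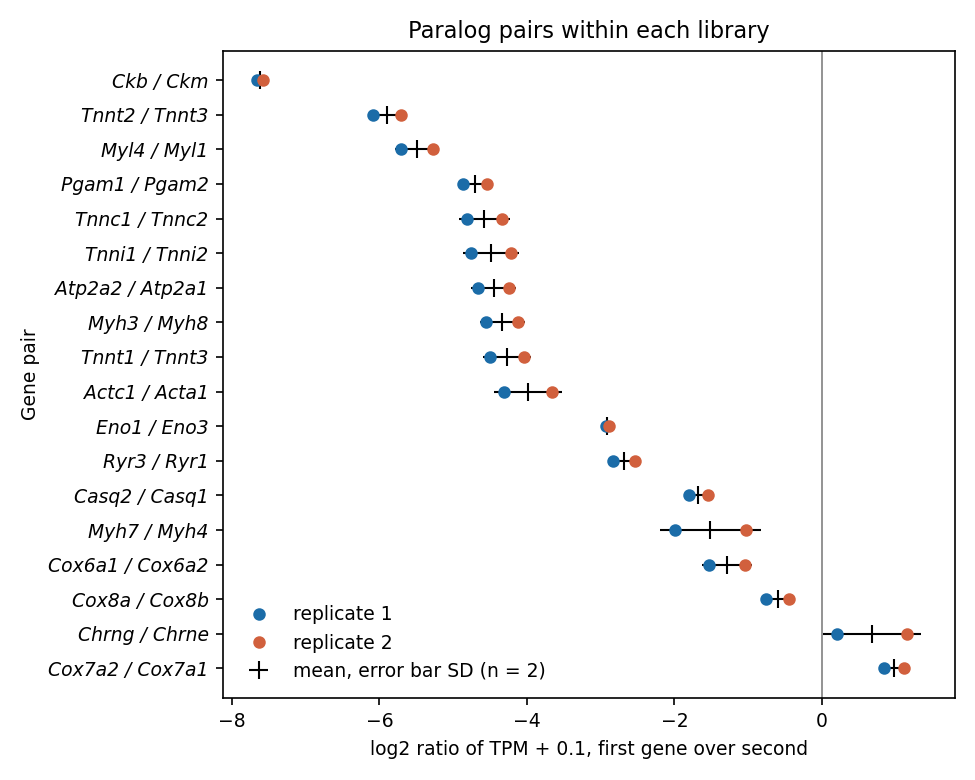
Log2 ratio of TPM plus 0.1 within each library for 18 gene pairs, first gene over second, with a point for each animal, a tick for the mean and a bar for the SD (n = 2). The pairs Chrng over Chrne and Cox7a2 over Cox7a1 lie above 0 and the other 16 below it.

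Fast contractile genes as a group were higher than slow ones. The fast list, with all 15 members at 1 TPM or more, had a median of 775 ± 70.6 TPM. Its highest members were Acta1, Mylpf, Myl1 and Tnnt3 (4071 ± 486 TPM), of which Acta1 was paired above with early Actc1, not with a slow gene. The slow list, with all 12 members at 1 TPM or more, had a median of 195 ± 8.97 TPM, led by the slow myosin-binding protein Mybpc1 (928 ± 28.5 TPM), the ventricular and slow light chain Myl2 (340 ± 25.2 TPM), Casq2 (242 ± 8.92 TPM) and Myh7 (227 ± 28.7 TPM). The fast median exceeded the slow median by 1.99 ± 0.20 on the log2 scale, or 3.98-fold, and by 3.31 in counts not divided by length. The 8 developmental contractile genes had a median of 116 ± 10.8 TPM, with Myh8, Actc1 (860 ± 236 TPM), Myh3 (233 ± 35.7 TPM) and Myl4 (155 ± 24.0 TPM) the highest.

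Genes that couple electrical excitation to calcium release were expressed together with the contractile genes. Triadin, Trdn, stood at 266 ± 25 TPM, the ryanodine receptor Ryr1 at 168 ± 4.87 TPM, and the calcium channel subunits Cacna1s and Cacnb1 at 129 ± 11.2 and 90.5 ± 11.2 TPM. In this list 11 of 12 members reached 1 TPM, with a median of 75.9 ± 2.71 TPM, and the exception, phospholamban (Pln), chosen after its value was seen, stood at 0.370 ± 0.0283 TPM. All 12 genes of the neuromuscular junction reached 1 TPM, with a median of 14.1 ± 0.354 TPM. The highest were utrophin (Utrn, 44.2 ± 7.69 TPM), the receptor subunits Chrnb1 (38.7 ± 0.0354 TPM) and Chrna1 (19.3 ± 0.651 TPM), and acetylcholinesterase (Ache, 29.2 ± 1.76 TPM). The fetal subunit Chrng stood at 10.98 ± 1.23 TPM beside 6.99 ± 2.45 TPM for adult Chrne, whose value was 8.72 TPM in replicate 1 and 5.26 TPM in replicate 2.

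Myogenic progenitor and cell cycle genes were present at moderate levels. Of 15 satellite cell and myoblast genes 14 reached 1 TPM, with a median of 17.4 ± 0.933 TPM. The differentiation factor Myog stood at 83.4 ± 8.66 TPM, the laminin receptor Itga7 at 60.4 ± 0.276 TPM, Myf6 at 55.2 ± 16.2 TPM and the fusion protein gene Mymk at 44.5 ± 0.834 TPM. Pax7, the marker of satellite cells, was chosen after its value was seen and stood at 8.34 ± 1.05 TPM. Pax3 stood at 0.0450 ± 0.0354 TPM, from 2 and 7 counts. All 15 cell cycle genes reached 1 TPM with a median of 15.9 ± 1.48 TPM, and the highest were Pcna (38.2 ± 1.13 TPM), Top2a (37.7 ± 3.47 TPM), Mki67 (27.3 ± 3.11 TPM) and Cdk1 (24.1 ± 3.73 TPM).

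Imprinted genes that govern fetal growth were among the most abundant transcripts. H19 stood at 8035 ± 571 TPM and the growth factor Igf2 at 5050 ± 365 TPM, and these neighbours lie on chromosome 7. The maternally expressed noncoding RNAs Meg3 and Rian, which share a domain on chromosome 12, stood at 2621 ± 353 and 2104 ± 102 TPM. All 18 imprinted genes of the list reached 1 TPM, with a median of 275 ± 10.9 TPM and a sum of 23004 ± 1546 TPM. The share of each parental allele was not analysed here.

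Glycolytic genes were higher than genes of oxidative metabolism. The 16 glycolysis and glycogen genes had a median of 470 ± 43.9 TPM, with Gapdh at 2288 ± 270 TPM, Aldoa at 2081 ± 192 TPM, Eno3 at 1546 ± 143 TPM and the glycogen phosphorylase Pygm at 807 ± 101 TPM. The 22 genes of oxidative metabolism had a median of 148 ± 2.40 TPM, led by the ADP/ATP carrier Slc25a4 (598 ± 64.4 TPM), Cox4i1 (525 ± 18.9 TPM), Ndufa4 (360 ± 31.9 TPM) and Cox8b (291 ± 23.9 TPM). All members of both lists reached 1 TPM. The difference of the medians exceeded the spread between the animals, and it compares genes that were not chosen as matched pairs.

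Markers of nonmuscle cells were led by matrix genes. The fibroblast and matrix list, with all 14 members at 1 TPM or more, had a median of 93.3 ± 2.78 TPM, and the collagens Col1a1 (2684 ± 61.7 TPM), Col3a1 (2293 ± 22.4 TPM) and Col1a2 (1602 ± 42.5 TPM) and the matrix protein Postn (670 ± 14.2 TPM) were its highest genes. All 8 tendon genes were at 1 TPM or more (median 24.1 ± 1.45 TPM), with Tnmd at 107 ± 4.20, Thbs4 at 83.2 ± 7.77, Fmod at 75.1 ± 0.0495 and Kera at 29.5 ± 1.38 TPM. All 9 endothelial genes (median 18.8 ± 0.948 TPM) and all 9 pericyte and smooth muscle genes (median 27.3 ± 1.17 TPM) were also at 1 TPM or more. Among them were Cdh5 at 67.0 ± 0.792, Egfl7 at 64.6 ± 10.1, Pecam1 at 50.0 ± 0.240 and Esam at 20.4 ± 3.10 TPM, and Acta2 at 180 ± 6.87, Rgs5 at 55.5 ± 3.65, Tagln at 45.4 ± 4.79 and Abcc9 at 45.1 ± 3.44 TPM. The 11 macrophage genes had a median of 13.3 ± 0.212 TPM, with Mrc1 at 22.0 ± 2.45, Lyz2 at 20.7 ± 1.90, Csf1r at 18.8 ± 1.63 and C1qb at 14.7 ± 1.45 TPM.

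Blood and skeletal markers ranged from high to undetected. Haemoglobin genes of red cells were abundant, with Hba-a1 at 260 ± 19, Hbb-bs at 243 ± 31.6, Hba-a2 at 191 ± 26.7 and Hbb-bt at 34.3 ± 1.34 TPM, and 6 of 9 erythroid genes reached 1 TPM (median 3.89 ± 0.750 TPM). Reads of Hba-a1 and Hba-a2, which are near-identical, are split between them by estimation. Of 7 neutrophil and marrow genes 2 reached 1 TPM, S100a9 (2.34 ± 1.47 TPM) and S100a8 (1.87 ± 0.0283 TPM), with Ngp at 0.545 ± 0.205 and Ltf at 0.520 ± 0.0424 TPM and a list median of 0.475 ± 0.106 TPM. Elane stood at 0.0600 ± 0.0283 TPM, from 1 and 2 counts. Of 10 cartilage and bone genes 3 reached 1 TPM, Col2a1 (15.3 ± 0.700 TPM), Acan (3.32 ± 0.148 TPM) and Sox9 (1.95 ± 0.453 TPM), with Dmp1 at 0.735 ± 0.0919 TPM and a list median of 0.258 ± 0.0813 TPM. Sp7 stood at 0.0700 ± 0.0283 TPM, and Matn1 and Bglap had 0 counts in both libraries, which allows up to 0.0539 and 0.301 TPM in replicate 1 and 0.0579 and 0.371 TPM in replicate 2.

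Sex-linked genes matched the male label of both animals. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d stood at 28.9 ± 0.891, 22.8 ± 0.552, 9.57 ± 0.332 and 5.39 ± 1.05 TPM, and Xist, the RNA that silences an X chromosome in female cells, at 0.0500 ± 0.0283 TPM. Stress and clock genes were low to moderate, with all 12 immediate early and stress genes and 12 of 13 clock genes at 1 TPM or more. The list medians were 8.39 ± 0.916 and 10.5 ± 0.325 TPM. The highest immediate early genes were Jun (28.9 ± 2.22 TPM), Dusp1 (18.5 ± 1.44 TPM), Egr1 (12.1 ± 4.53 TPM) and Btg2 (11.1 ± 0.212 TPM). The highest clock genes were Tef (47.0 ± 0.905 TPM), Cry2 (23.2 ± 1.31 TPM), Nr1d2 (21 ± 0.686 TPM) and Per1 (20.7 ± 0.834 TPM), and Ciart, chosen after its value was seen, stood at 0.735 ± 0.106 TPM.

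The 2 libraries differed most in genes of the epidermis and hair follicle, which were far higher in replicate 2. The epidermal keratins Krt1 and Krt10 stood at 0.330 and 3.33 TPM in replicate 1 and at 269 and 282 TPM in replicate 2. Krtdap stood at 5.68 and 65.8 TPM and the basal keratin Krt5 at 0.160 and 60.8 TPM. All 6 genes of the epidermis list were higher in replicate 2, 5 of them by over 2-fold, and the median log2 ratio of depth-normalised counts (CPM) was 8.24, above every one of 10000 random lists of the same size and mean expression (percentile 100). A set of 252 symbols was picked by first letters shared with keratin, cornified-layer, desmosomal, Klk, Serpinb and Lypd genes, among others. These families, called skin families here, took 0.0110% of counts in replicate 1 and 0.337% in replicate 2. They need not hold skin genes only.

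The 10 largest ratios among genes with a mean count of 100 or more were all of this kind. Replicate 1 had 1 count of the inner root sheath keratin Krt25, 2 of Krt71, 6 of the cornified-layer protein hornerin (Hrnr), 23 of Krt1 and 37 of filaggrin (Flg). Replicate 2 had 1136, 2240, 6491, 17262 and 27232 counts of these genes. Their log2 CPM ratios were 9.65 (95% counting interval 7.75 to 15.54), 9.89 (8.36 to 13.26), 10.05 (9.04 to 11.61), 9.61 (9.05 to 10.29) and 9.59 (9.14 to 10.11). The basal keratin Krt14 had 3 and 1879 counts (9.15, interval 7.83 to 11.65), loricrin (Lor) 2 and 1171 (8.96, 7.42 to 12.33), the protease inhibitor gene Spink5 1 and 394 (8.12, 6.22 to 14.01) and the hair keratin Krt83 1 and 392 (8.12, 6.21 to 14.01). The desmosomal cadherin Dsg1a had 0 counts in replicate 1 and 1133 in replicate 2, which makes it at least 400-fold higher. These intervals cover counting error only.

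Myelin and fat genes were also higher in replicate 2. The myelin gene Mbp stood at 85.4 TPM in replicate 1 and at 204 TPM in replicate 2. Pmp22 stood at 152 and 254 TPM and Prx at 15.6 and 35.6 TPM. All 9 genes of the Schwann cell list were higher in replicate 2, 3 of them by over 2-fold, with a median log2 ratio of 0.94 (percentile 100). All 9 adipocyte genes were higher in replicate 2, 5 of them by over 2-fold, with a median of 1.01 (percentile 100). The lipid carrier Fabp4 stood at 192 and 281 TPM, Cfd at 35.0 and 58.1 TPM, adiponectin (Adipoq) at 14.6 and 32.9 TPM and perilipin (Plin1) at 10.8 and 35.0 TPM. The epidermal genes were higher in the same library, but with 2 libraries a shared direction cannot show a shared source.

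Contractile and metabolic genes differed between the libraries by far less. In replicate 2, 14 of 15 fast contractile genes were lower (median log2 ratio -0.23, percentile 0.01), as were 14 of 16 glycolysis and glycogen genes (-0.19, percentile 0), 20 of 22 oxidative genes (-0.20, percentile 0), 12 of 14 satellite cell and myoblast genes (-0.17, percentile 0.24) and 9 of 12 excitation-contraction coupling genes (-0.16, percentile 0.72). Higher in replicate 2 were 7 of 8 developmental contractile genes (0.30, percentile 100), 9 of 12 slow contractile genes (0.10, percentile 99.6), 14 of 15 cell cycle genes (0.12, percentile 99.4) and all 11 macrophage genes (0.17, percentile 99.2). No gene of these 9 lists with a mean count of 10 or more differed by over 2-fold. With the epidermis, Schwann cell and adipocyte lists, 12 of 24 lists lay outside the middle 95% of random lists, and all 12 kept that call under the other filter and the other quantification tried. Their signs held under these and under the other scalings, which cannot move the percentile.

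The other 12 lists lay within the middle 95%. Their median log2 ratios were -0.11 for the myosin heavy chains, 0.06 for the neuromuscular junction, -0.05 for imprinted growth genes, -0.01 for fibroblast and matrix, 0.02 for tendon, -0.08 for endothelial and -0.05 for pericyte and smooth muscle genes. They were 0.93 for neutrophil and marrow, 0.11 for erythroid, 0.10 for cartilage and bone, 0.04 for immediate early and stress and -0.08 for clock genes. The neutrophil and marrow value rested on 4 genes with few counts. The imprinted, fibroblast, endothelial and pericyte medians changed sign when counts were scaled to the spike-ins, which added 0.08 to every log2 ratio.

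**Figure D3:**
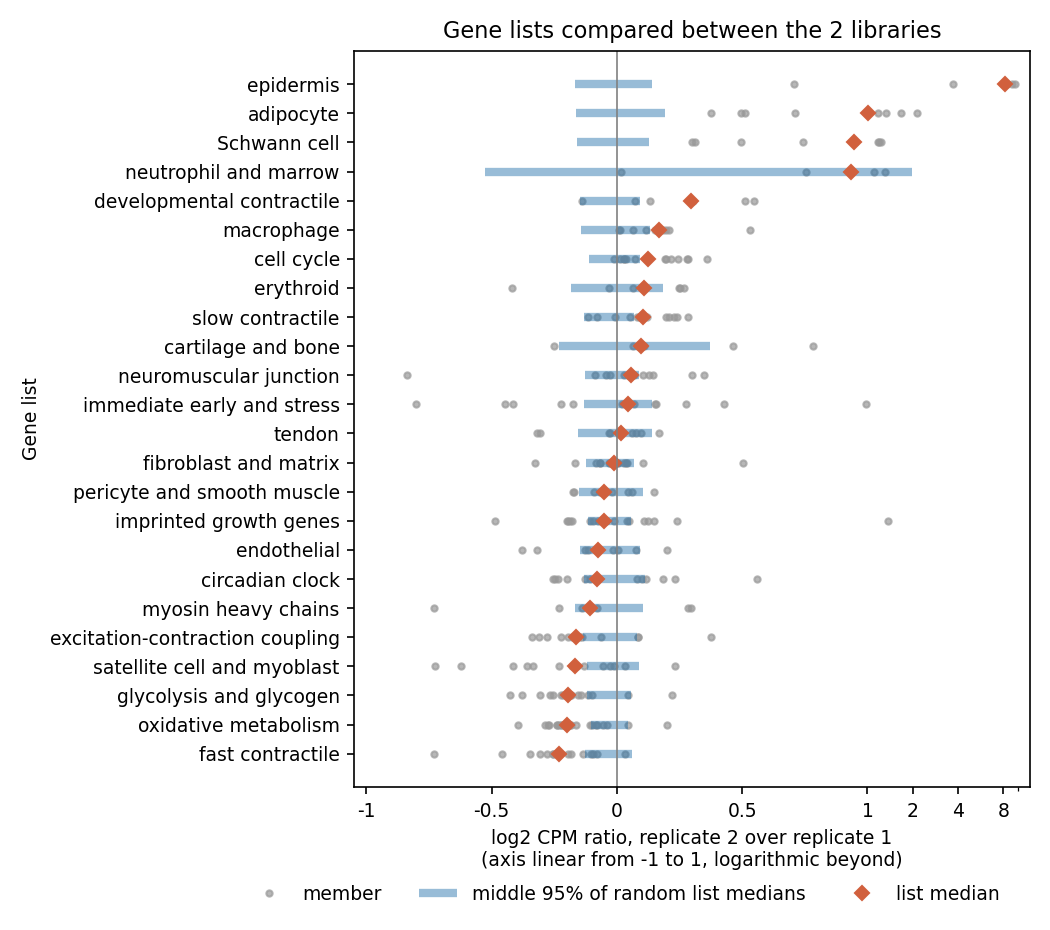
Log2 ratio of CPM, replicate 2 over replicate 1, for 24 gene lists, with grey points for genes, diamonds for list medians and bars for the middle 95% of medians of 10000 random lists of matched size and expression. The epidermis, adipocyte and Schwann cell medians lie at 8.24, 1.01 and 0.94, and with spike-in scaling the imprinted, fibroblast, endothelial and pericyte medians, here just below 0, lie above it.

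Across all genes the animals ranked transcripts alike. Across 17998 genes with a mean count of 10 or more, Spearman's rho of TPM was 0.970 and Pearson's r of log2 TPM was 0.958, across genes, which are not independent replicates. The common biological coefficient of variation estimated by edgeR was 0.270, and 0.202 without the skin families and the epidermis, Schwann cell and adipocyte lists, a setting chosen after seeing the data. Of 12421 genes with a mean count of 100 or more, 208 (1.67%) differed by over 2-fold, 195 higher in replicate 2 and 13 higher in replicate 1. The 13 include entries of Nnt and Rnu3a, loci whose counts were split between overlapping gene identifiers. In 100 simulated pairs of libraries with counting noise alone the highest number was 0, which gives the level of counting noise only. Of the 68 genes counted in the skin families and those 3 lists, 51 differed by over 2-fold, and without them 157 genes remained over 2-fold. Of 92 genes over 8-fold higher in replicate 2, 43 belonged to these families and lists. The families were picked by the first letters of symbols, which left out skin genes of other names, such as Spink5 (log2 ratio 8.12). The 157 genes and the coefficient of 0.202 therefore still include such genes. With genes of a mean count of 10 or more the number over 2-fold was 1111.

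Transcript use of the contractile genes was alike in the 2 animals but depended on the quantification. Myh8 was read almost wholly as 1 transcript, Myh8-201 of 6149 nt, with 98.2% ± 0.148 of the gene. Acta1-201 held 98.9% ± 0.156, Actc1-201 and Myh4-201 100% each, and Atp2a1-201 69.6% ± 0.516. By the quantification made directly from reads Acta1-201 held only 54.0% ± 0.0472, whereas Actc1-201 and Myh4-201 again held 100% and Atp2a1-201 68.6% ± 0.432. Tnnt3, a gene with 27 annotated transcripts and extensive alternative splicing, had a leading transcript of 28.4% ± 0.403. Of 47 genes of the contractile lists and pairs with 2 or more transcripts, 46 had the same leading transcript in both animals and 18 had one over 90%. The second quantification, made directly from reads, gave the same leading transcript for 29 of the 47. It differed for Myh1, Myh2, Tnni2, Tnnt3, Myl1 and Pvalb among the fast genes, where for example Tnni2-201 held 97.4% ± 0.0212 by the first and 1.98% ± 0.208 by the second. Across all genes with 10 TPM or more the leading transcript was the same for 73.7% ± 0.377.

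The 2 quantifications differed most for short genes. Rn7s1, Rn7s2 and Rn7sk together had 33.8% of TPM by the alignment-based quantification and 0 by the quantification made directly from reads. Of genes with a mean count of 100 or more, 79 were shorter than 300 nt and 77 of these had under 1 count over both libraries in the latter, and the median log2 ratio of its counts to the former was -10.45 ± 0.30. The median was -7.86 ± 0.16 for 75 genes of 300 to 400 nt, -1.05 ± 0.05 for 120 genes of 400 to 500 nt and -0.10 ± 0.003 for 950 genes of 500 to 1000 nt. It was 0.04 ± 0.002 and 0.11 ± 0.001 for the 2 longer classes. The muscle-type subunit Cox7a1, whose leading transcript Cox7a1-201 is 393 nt long, held 96.2% ± 0.523 in that transcript by the first quantification and 0% by the second.

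**Figure D4:**
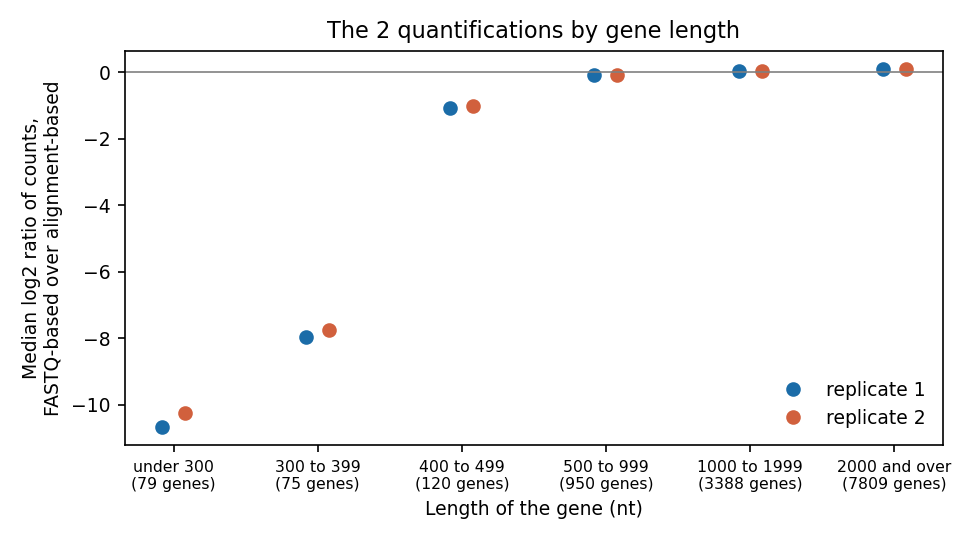
Median log2 ratio of counts, the quantification made directly from reads over the alignment-based one, by gene length (nt), with a point for each library. The mean of the 2 libraries is -10.45 for genes under 300 nt and 0.04 for genes of 1000 to 2000 nt.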

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

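Of the tests in this part, those on melanocyte genes and on the 2 kinds of Schwann cell genes were chosen before their results were seen, and all the others only after the result was seen. The design has 1 group, so no biological explanation was tested against a group. Bootstrap SDs in this part used 2000 draws. With 1 library per animal they can describe the spread across genes of the lists only, not the spread between animals or dissections. A signal was seen in data outside the main measurement: the phiX174 sequence, a control added in sequencing, had 50 expected counts in replicate 1 and 50 in replicate 2, above the 3 counts that a count of 0 allows.

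Epidermal and hair follicle genes were far higher in replicate 2, with a list median of 8.24 on the log2 scale and Krt10 and Krt1 at 282 and 269 TPM. The tables argue against a different assignment of reads between keratin paralogs, since the quantification made directly from reads gave 8.17, and against a library of another tissue, since the fast contractile list differed by a median of only -0.23. A candidate explanation is RNA from skin in the replicate 2 library: the melanocyte list, whose 4 measurable members of 7 are pigment cell genes and not epidermal genes, had a median of 1.32 (bootstrap SD 0.23), with Pmel at 1.63 and 3.47 TPM and Dct at 1.05 and 2.71 TPM. These 2 melanocyte genes were already at 1 TPM or more in replicate 1. The melanocyte list (percentile 98.5) rose by a size near that of the myelin (1.20) and adipocyte (1.01) lists, far below that of the epidermis list. Carry-over from a library that holds skin would raise it too, so the list does not decide between these sources. Reads carried over from another library of the sequencing pool stay open, because the share of skin families, 0.337% of counts in replicate 2, does not tell where they came from and other libraries of the pool were not analysed here.

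Myelin and adipocyte genes were also higher in replicate 2. A lower share of muscle RNA would raise the markers of every other cell type alike, but the Schwann cell median lay 0.96 (bootstrap SD 0.24) above the median of the fibroblast, tendon, endothelial, pericyte and macrophage list medians, which ranged from -0.08 to 0.17. More Schwann cells of every kind, as the whole explanation, are argued against by the myelin list, at 1.20, lying 0.76 (bootstrap SD 0.24) above the list of immature or non-myelin Schwann cells, at 0.44, a margin over the bound of 0.5 that was only slightly wider than that SD. The latter list was itself higher in replicate 2 for 8 of 8 genes (percentile 99.8), so a general rise in Schwann cells stays open for part of the difference. Fat and nerve carried along with skin cannot be told apart from other sources, since the adipocyte median of 1.01 has no skin profile to be set against. A difference between the 2 animals in myelination or fat stays open and untested.

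Myh4 was lower and slow and embryonic contractile genes were higher in replicate 2. Dilution of muscle RNA by other tissue, if it moved slow and fast genes alike, would leave no gap between their lists. The slow list median lay 0.34 (bootstrap SD 0.07) above the fast one, which argues against dilution as the whole explanation. This gap is part of the pattern itself, and dilution stays open for part of the difference. Less mature fibres in replicate 2 stay open, as a hypothesis that may explain part of the pattern: early muscle genes (median 0.07, higher for 5 of 8) lay 0.31 (bootstrap SD 0.16) above later-rising genes (median -0.24, lower for 12 of 13), and 0.44 (bootstrap SD 0.14) above them, with a median of 0.20, without Peg3 and Cdkn1c, whose values had been seen before the list was written. The early list of 8 genes by itself lay within the middle 95% of random lists (percentile 90.2). Some other genes of developing muscle did not move with the early list. Satellite cell and myoblast genes, which include the differentiation factor Myog, were lower (median -0.17, lower for 12 of 14). Myh8, the later gene of its pair with Myh3, was also lower (-0.14). Imprinted growth genes, a list that shares Peg3 and Cdkn1c with the early list, had a median of -0.05, or 0.025 with spike-in scaling. These groups do not hold early genes only, so they do not decide on less mature fibres. A larger portion of slow muscle in the sample cannot be told apart, because the median of Myh3, Actc1, Myl4, Tnnt2 and Myl6b exceeded the slow list median by 0.20 (bootstrap SD 0.13), which lies between the values that would favour or exclude it. Both animals carry the same age of 4 days in the labels, and a difference within that day was not tested.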

How the results depend on the processing

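No paired analysis was possible because there is only 1 group. Another scaling moves every gene and random list alike, so it cannot change whether a gene list lies outside the middle 95% of random lists. Apart from those scalings of the lists and from leaving out a library, 196 alternatives were run: 157 stayed within bounds, 38 moved beyond them and 1 reversed. Among the 157 were 30 for the genes of largest ratio, of which only 10 used the other quantification. The rest of the 30 were scalings, whose shifts of 0.08 or less were too small to leave the counting intervals. The fast minus slow difference over members at 1 TPM or more could not move either, since all members reached that level. The bounds were the spread of the 2 libraries for a level or ratio, 1.5 times for a number of genes or lists, the same 2 decimals for a correlation or coefficient, the counting interval for a gene of largest ratio, where it had one, and the call for a list. Within them the number of genes at the minimum TPM in both libraries ranged from 9295 at 5 TPM to 15427 at 0.5 TPM, against 13579 at 1 TPM. Under the other filter and quantification all 48 alternatives of the gene list comparisons kept their call, and 0 medians changed sign. Under the other scalings 4 medians changed sign, all with spike-in scaling and all within the middle 95%: imprinted genes to 0.025, fibroblast to 0.065, endothelial to 0.0015 and pericyte to 0.028. By the quantification made directly from reads, Myh8 held 74.3%, Myh7 2.69% and the adult fast chains 19.04% of sarcomeric myosin heavy chain TPM, and the log2 ratios were -4.62 for Actc1 to Acta1, -5.60 for Tnnt2 to Tnnt3, -4.02 for Tnni1 to Tnni2 and -0.68 for Cox6a1 to Cox6a2. In counts not divided by length, Myh8 held 77.5% and Myh7 2.62%, the ratio of Tnni1 to Tnni2 was -3.83, the fast minus slow difference was 3.31 and the ratio of Cox8a to Cox8b reversed to 0.19; dividing by length is by construction what separates these from the TPM values. For the second quantification the cause was not tested. Spearman's rho was 0.927 over genes with any count and 0.976 at a mean count of 100 or more, and the edgeR coefficient of variation was 0.276 at a mean count of 1 or more and 0.2003 at 100 or more. That coefficient was 0.202 without skin families and the epidermis, Schwann cell and adipocyte lists, a setting chosen after seeing the data. The number of genes over 2-fold was 1111 at a mean count of 10 or more, where more genes of low count enter, and ranged from 157 to 226 under the others. The leading transcript was the same for 74.2% of genes at 1 TPM or more and 64.9% at 100 TPM or more, and the cause was not tested. Leaving out either library leaves the value of the other, which lies within the spread by construction, so it says nothing about stability: Myh8 ranged from 75.4% to 77.0%, the adult fast chains from 14.3% to 18.2%, Myh3 from 3.21% to 4.44%, Myh7 from 3.19% to 4.24%, the fast minus slow difference from 1.85 to 2.13 and Chrng to Chrne from 0.21 to 1.16. Scaling to the spike-ins added 0.08 to each log2 ratio between the libraries. Depth limits genes of few counts, such as the neutrophil and marrow list, and the keratins of 1 to 3 counts in replicate 1.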

Other observations

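The genes described here were chosen after the files were opened, and the histone genes, Gm6565 and the 2 shared loci after their values were seen. Genes of hindlimb patterning were detected, and no enrichment was tested. All 8 hindlimb genes were at 1 TPM or more, as were 13579 of 55536 annotated genes in both libraries, with Hoxc10 at 17.2 ± 1.73 TPM, Hoxa10 at 12.2 ± 1.37 TPM and Hoxd9 at 4.43 ± 0.827 TPM (SD, n = 2), and the hindlimb regulators Tbx4 and Pitx1 stood at 2.495 ± 0.205 and 1.98 ± 0.240 TPM. Tbx5, the forelimb counterpart of Tbx4, stood at 0.0650 ± 0.0354 TPM, from 6 and 4 counts, and Hoxb1 had 0 counts in both libraries, which allows up to 0.0825 TPM. Of the 5 forelimb or anterior genes 2 reached 1 TPM, Hoxc4 (2.91 ± 0.148 TPM) and Hoxc5 (1.87 ± 0.226 TPM), which lay at the level of Tbx4 and Pitx1. Between the animals the hindlimb list had a median log2 ratio of -0.24 (percentile 0.54, lower in replicate 2 for 7 of 8 genes), and 3 measurable forelimb or anterior genes had 0.08 (percentile 54.7).

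Growth signalling and replication-dependent histone genes were both well represented. Igf2 stood at 5050 ± 365 TPM beside Igf1 at 73.9 ± 2.16 TPM, the binding protein Igfbp5 at 137.5 ± 2.84 TPM, myostatin (Mstn), which limits muscle growth, at 30.2 ± 4.12 TPM, and its antagonist follistatin (Fst) at 17.5 ± 1.46 TPM. The 8 growth signalling genes had a median log2 ratio between the animals of -0.03 (percentile 46.5). Of 67 clustered histone genes 63 reached 1 TPM, with a sum of 7224 ± 661 TPM and the highest values for Hist2h2aa2 (491 ± 20.5 TPM), Hist1h4k (365 ± 24.4 TPM) and Hist1h4h (330 ± 28.7 TPM). These are short genes with near-identical copies. The quantification made directly from reads gave Hist2h2aa2 0 TPM and Hist1h4h 676 ± 102 TPM, so single histone values are uncertain.

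Among genes lower in replicate 2 with a mean count of 100 or more, Rnu3a, Nnt and the processed pseudogene Gm6565 stood apart, with the next gene, Gm45140, at a log2 ratio of -1.56. For Nnt and Rnu3a the difference lay between 2 overlapping gene identifiers of 1 locus. On chromosome 13, the Nnt entry at 119335528 to 119408952 had 591 counts in replicate 1 and 9.62 in replicate 2, while the entry at 119335448 to 119408997 had 3657 and 3934. Their sum was 4248 and 3944 counts. On chromosome 10, the Rnu3a entry at 40258467 to 40258679 had 526 and 0 counts and the entry ending at 40258680 had 452 and 1055, with sums of 978 and 1055. The quantification made directly from reads gave the first Nnt entry 3137 and 2895 counts. Gm6565, on chromosome 6 at 100604683 to 100605120, had 232 and 4.43 counts, a log2 ratio of -5.47 (95% counting interval -7.66 to -4.40). It had 0 TPM by the quantification made directly from reads, and where its reads came from was not tested. The deposited TPM bounds of the 2 libraries overlapped (1.01 to 22.2 and 0.000133 to 17.3). The TPM of replicate 1, 23.4, lay above its own upper bound, so the overlap says little about the difference.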
